A study of Drosophila melanogaster with 12 samples.

How the data were processed

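Per the labels, the molecule was total RNA, and fat bodies were dissected from Drosophila melanogaster larvae 96 hours after egg laying, frozen, extracted with Trizol and made into libraries with a directional kit. The 12 libraries were 6 of r4-Gal4 crossed to wild type, called control here, and 6 of r4-Gal4 driving an RNAi construct against TFAM, called TFAM RNAi. r4-Gal4 is a driver line that expresses the yeast activator Gal4 mainly in the larval fat body. The titles numbered the control replicates 2, 3, 5, 6, 7 and 8 and the TFAM RNAi replicates 3 to 8. The labels did not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be partly technical.

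The authors deposited a table of TPM, the transcript abundance scaled within each library, for 34213 RefSeq transcripts, in which each library sums to 1000000. They also deposited p-values and q-values of likelihood ratio and Wald tests, with columns named as sleuth writes them; sleuth is named in the submitters' processing notes, without a version. The quantifier, its settings and the genome build were not given in the sources used here. The authors' Wald coefficients are on a natural log scale per the deposited values: over 1498 transcripts above 50 TPM in all 12 libraries, the coefficient had a slope of 0.999 on the difference of mean natural-log TPM. The authors' deposited list of transcripts heads this coefficient as a log2 value. Among its unheaded columns is one of ratios that are 2 to the power of that coefficient in 1758 of 1758 rows. These ratios were not used as folds. TPM keeps no depth, so the depth behind each value is unknown and no counting interval is given. No column of per-sample values was left out.

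Gene names in the authors' table were damaged in part: 94 transcripts of 40 genes, all of them complex I subunits whose symbols start with ND-, carried the name ubiquinone, 181 transcripts of 77 genes carried only digits, and 6 genes had become dates. Transcripts were therefore named by RefSeq accession through a RefSeq gene table of the assembly Release 6 plus ISO1 MT, which matched 34056 of them (99.54%). The others took the authors' name, which for 40 transcripts was in neither reference table. The reference table gave names and gene order only, and no coordinates are printed because the build of the files was not named. TPM were summed over transcripts to 17137 genes. The table held 0 mitochondrially encoded genes, so the lists of mitochondrially encoded subunits and ribosomal RNAs were not analysed here. Of the genes with a mean of at least 1 TPM, 123 had the same value in all libraries as another gene, such as mtTFB1 with Ccdc56 and PolG2 with GatC, and their values belong to either gene.

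Genes with a mean of at least 1 TPM over all 12 libraries, 9951 in number, were tested with limma (version 3.58.1 in R 4.3.3: lmFit and eBayes with trend) on log2(TPM + 1), without a block. P-values were two-sided, Benjamini-Hochberg adjusted over all tested genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are TFAM RNAi over control on the log2(TPM + 1) scale, which understates the change of low genes; SE is the moderated standard error. TPM are means ± SD over 6 libraries. The comparison, the tests, the alternatives, 41 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members, 38 in number, were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera asks whether a list's genes moved relative to the other genes. The lists were also tested with camera at an estimated correlation and with fry. Fry, as used here, asks whether a list's genes shifted in 1 direction as a whole, not relative to the other genes, so its calls answer another question. A list with both rises and falls can therefore go uncalled by fry although its genes changed. The named genes were 13 set in advance (TFAM, egr, upd2, daw, ImpL2, Gbp1, Gbp2, CCHa2, Ilp6, Thor, bmm, Ldh and Lsp2), the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 TPM and no overlap between the groups, and up to 4 called members of each list with the smallest adjusted p.

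On simulated data with the real means and spreads of the 9951 genes, 200 of them changed, the test for TFAM RNAi against control recovered 31.3% of genes changed by 0.5 on the log2 scale, 65.7% of those changed by 1 and 95.5% of those changed by 2, and called 7 unchanged genes. Genes were drawn independently of each other, so the 7 gives no error rate for the real libraries. In the same simulation an exact rank-sum test recovered 0% at each size, and a replicate block 6, 38.8 and 77.3%. The smallest exact rank-sum p in 6 against 6 is 0.00216, and 200 changed genes among 9951 are too few for it to pass the adjustment. The 0% was thus fixed by the simulation, and in the real libraries this test called 1862 genes. The simulated libraries shared no replicate effect and the block used 10 of them, so its recovery does not carry over to the real libraries either. Alternatives were 2 other pseudocounts, no filter and a filter at 5 TPM, median-ratio scaling, quantile normalization, eBayes without trend and with the robust option, array weights, an exact rank-sum test, a replicate block, single transcripts, and each library left out in turn. Added after the data were seen were a fit without the 4 libraries richest in muscle, midgut or salivary gland markers and a fit of the block's 10 libraries without the block. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.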

Results

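Fat body transcriptomes were measured by RNA sequencing in 6 control libraries (r4-Gal4 crossed to wild type) and 6 TFAM RNAi libraries, all from larvae 96 hours after egg laying. The fat body is the larval organ of nutrient storage, humoral immunity and endocrine signalling. TFAM is a factor that packages mitochondrial DNA and takes part in its transcription. The comparison asked which fat body transcripts differed when TFAM was knocked down in this tissue. Between 8684 and 10325 genes reached 1 TPM in a library. Nplp2, the most abundant transcript in 10 of the 12 libraries, took 5.62 to 7.0% of the TPM in the controls. Pearson correlations of log2 values were 0.905 to 0.98 between control libraries and 0.932 to 0.984 between TFAM RNAi libraries. The first principal component held 37% of the variance and the second 23.3%.

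In TFAM RNAi fat bodies TFAM fell by 1.88 on the log2 scale, and 47 of 75 tested mitochondrial ribosomal protein genes fell while 0 rose. That count depended on the scaling: 14 fell and 0 rose under median-ratio scaling, and 14 fell and 2 rose under quantile normalization. Of 23 antimicrobial peptide and humoral effector genes 9 rose, led by the diptericin gene DptB, and 3 fell, among them PGRP-SC2 (log2 fold change −6.16). The larval serum protein gene Lsp1alpha and the odorant-binding protein gene Obp99b rose to 9791 and 5761 TPM. Of the secreted signals egr, Lst and CCHa2 were among those that fell, whereas Gbp1 and Gbp2 rose.

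TFAM (FBgn0038805) fell from 91.9 ± 8.21 TPM in control to 24.2 ± 1.92 TPM in TFAM RNAi (SD, n = 6 each). Its log2 fold change was −1.88 (SE 0.077, adjusted p = 5.2e-09), with all 6 TFAM RNAi libraries below all 6 controls. Reads from the RNAi hairpin, if any mapped to TFAM, would raise the measured level.

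Of 9951 genes tested, 1949 (19.6%) were called: 572 rose and 1377 fell. A change of at least 2-fold was seen in 586 of them, 170 higher and 416 lower. The libraries of the groups did not overlap for 1302 of the 1949 called genes. Chance separates 0.22% of genes in 6 against 6, but that rate holds for all genes, and the called ones were chosen for their difference. The share of called genes that rose was 29.3% and depended on the scaling: quantile normalization called 961 higher and 1075 lower, or 47.2% higher. Without the 4 libraries richest in markers of other tissues, a fit added after the data were seen, 1137 genes were called higher and 1049 lower, and 1472 of the genes called from all libraries were called again in the same direction.

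Among called genes with a mean of at least 5 TPM and no overlap between the groups, CG14752 fell the most. It went from 2164 ± 494 TPM to 4.31 ± 1.16 TPM (log2 fold change −8.67, SE 0.17, adjusted p = 1.4e-11), CG1077 from 529 ± 289 to 0.882 ± 0.42 TPM and CG14949 from 363 ± 194 to 1.39 ± 1.01 TPM. PGRP-SC2, an amidase that degrades peptidoglycan, fell from 771 ± 242 to 9.37 ± 1.02 TPM (log2 fold change −6.16). Adenylate kinase 1 (Ak1) fell from 456 to 9.64 TPM, the ecdysone-synthesis cytochrome P450 gene sad from 55.5 to 0.539 TPM, CG45060 from 102 to 2.04 TPM and laza, a lipid phosphate phosphatase, from 267 to 8.15 TPM. The largest rises were those of DptB, a diptericin (1.54 ± 2.05 to 288 ± 273 TPM; log2 fold change 6.64, SE 0.67, adjusted p = 1.1e-05), and the long non-coding RNA CR44316 (0.649 to 135.5 TPM). The C-type lectin gene lectin-24A rose from 1.52 to 80.5 TPM. The means were 189 TPM for DptB without TFAM RNAi replicate 3, and in control 1.015 and 1.005 TPM without replicate 2 or 6. That of sad was 0.298 TPM without TFAM RNAi replicate 8 and the control means of lectin-24A and CR44316 were 0.233 TPM without replicate 2 and 0.339 TPM without replicate 6. The odorant-binding protein gene Obp99b rose from 147 ± 99.9 to 5761 ± 1808 TPM and the larval serum protein gene Lsp1alpha from 309 ± 263 to 9791 ± 3885 TPM (log2 fold change 5.28, SE 0.48, adjusted p = 5.3e-06). PGRP-SB1, DptA and AttC completed the 8 largest rises, at log2 fold changes of 4.58, 4.32 and 4.28.

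**Figure D1:**
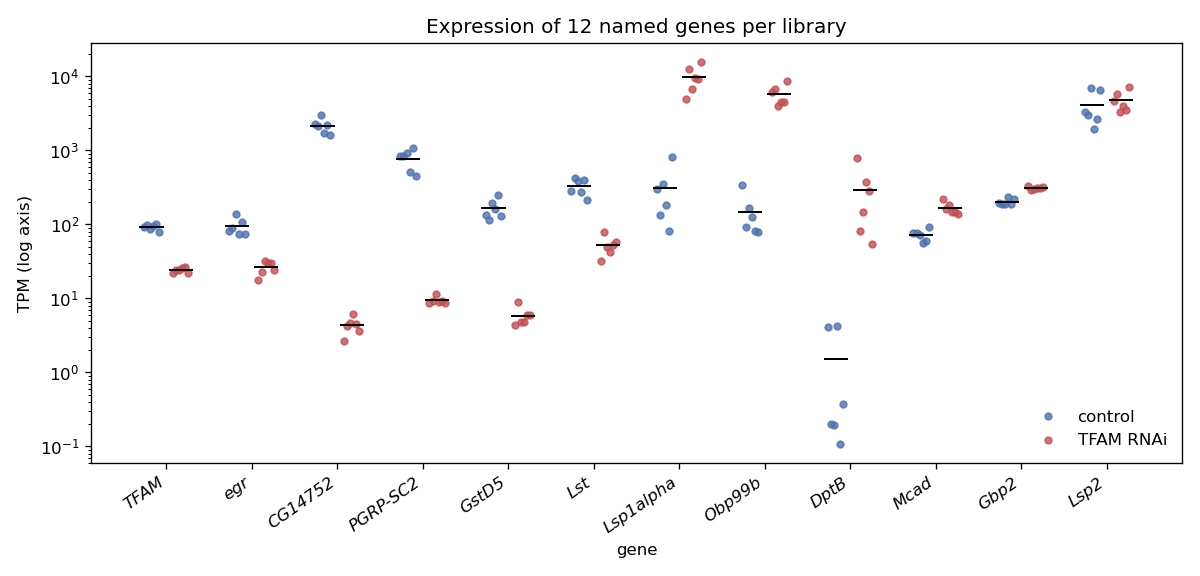
TPM of 12 named genes in each library on a log axis, with 6 control and 6 TFAM RNAi points per gene and a bar at each group mean. TFAM lay at 91.9 TPM in control and 24.2 TPM in TFAM RNAi on average, CG14752 at 2164 and 4.31 TPM, and Lsp2, which was not called, at 4050 and 4741 TPM.

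Of 75 tested mitochondrial ribosomal protein genes, 47 fell and 0 rose (57 fell when adjusted over the list alone), with a median log2 fold change of −0.31. mRpL36 fell from 286 ± 43.3 to 107 ± 17.4 TPM (log2 fold change −1.41, SE 0.12, adjusted p = 2.4e-06), mRpS2 from 134 to 63.3 TPM and mRpS23 from 80.4 to 46.0 TPM. Among 34 nuclear-encoded complex I subunit genes, 17 fell and 0 rose, also when adjusted over the list alone. ND-30 fell from 419 ± 16.7 to 243 ± 16.1 TPM (log2 fold change −0.78, adjusted p = 3.8e-07), whereas ND-49 fell by 0.27 and ND-23 by 0.31 on the log2 scale. Of 23 genes for complexes II, III and IV and cytochrome c, 13 fell and 0 rose (16 adjusted over the list alone); the succinate dehydrogenase genes SdhB (390 to 221 TPM, log2 fold change −0.82) and SdhD (198 to 151 TPM) and the cytochrome c oxidase gene COX7A (1546 to 1050 TPM) were among them. Of 13 ATP synthase genes 4 fell (4 adjusted over the list alone), ATPsyngamma, ATPsynD, ATPsynCF6 and ATPsynE, at log2 fold changes from −0.33 to −0.20. Of 14 genes for mitochondrial DNA maintenance and expression 4 fell (4 adjusted over the list alone): TFAM itself, PolG2 (48.2 to 20.3 TPM, log2 fold change −1.21), mtTFB1 (73.3 to 44.7 TPM) and mTerf3 (19.1 to 11.4 TPM). PolG2 and mtTFB1 share their values with GatC and Ccdc56. The number of falls depended on the scaling: median-ratio scaling left 14 mitochondrial ribosomal protein genes and 1 complex I gene lower, at medians of −0.30 and −0.18, and quantile normalization left 14 lower and 2 higher among the former, at a median of −0.10, and 4 lower among the latter, at a median of −0.04 against −0.19 without that scaling. The median of the mitochondrial DNA list went from −0.17 to −0.001 under quantile normalization, with 4 genes lower in both. Among the genes for complexes II to IV 3 fell under median-ratio scaling (median −0.21) and 11 under quantile normalization (median −0.18), and among those for ATP synthase 0 and 5. Under median-ratio scaling ND-49, ND-23 and the 4 ATP synthase genes were not called (adjusted p from 0.15 to 0.36), and under quantile normalization ND-49 was not called (adjusted p = 0.19). ATPsynE was also not called without the trend (adjusted p = 0.053) or without the 4 libraries richest in markers of other tissues (0.061).

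Camera called these 5 lists lower, with adjusted p = 6.7e-16 for mitochondrial ribosomal proteins, 2e-06 for complex I, 9e-07 for complexes II to IV, 0.024 for mitochondrial DNA maintenance and 0.04 for ATP synthase. The mitochondrial DNA list includes TFAM, the gene targeted by the RNAi, and was not tested without it, so its call is in part the knockdown itself. In all, camera called 10 of the 38 lists, 5 lower and 5 higher. No list was called with an estimated correlation, where the lowest adjusted p was 0.73. The call of the complex I list was lost under quantile normalization (adjusted p = 0.19). That of the mitochondrial DNA list was lost without control replicate 6 (adjusted p = 0.053), under quantile normalization (0.08) and with array weights (0.06). That of the ATP synthase list was lost under median-ratio scaling (adjusted p = 0.37), with a filter at 5 TPM (0.12), without the trend (0.11), and without any of control replicates 3, 6 and 8 and TFAM RNAi replicates 5, 6, 7 and 8 (adjusted p from 0.051 to 0.11).

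Of 18 genes of the TCA cycle and pyruvate entry, 8 fell and 1 rose, the same numbers as when adjusted over the list alone (camera adjusted p = 0.13). Under quantile normalization 1 fell and 1 rose, with the median moving from −0.23 to −0.05, under median-ratio scaling 4 fell and 0 rose, and without the 4 libraries 3 fell and 1 rose. Camera called the list lower without control replicate 2 (adjusted p = 0.042), with no filter (0.028) and without the 4 libraries (0.048). The falls included Mpc1, a subunit of the mitochondrial pyruvate carrier (390 to 301 TPM), its relative CG9399 (227 to 157 TPM) and Scsalpha1 (383 to 317 TPM), whereas malate dehydrogenase 2 (Mdh2) rose from 617 to 793 TPM. Of 18 genes of import, dynamics and biogenesis, 2 rose and 2 fell, the same numbers as when adjusted over the list alone. The list's median was −0.02, its mean 0.02 and its camera direction higher; the median turned to 0.14 under quantile normalization, with 4 rising and 0 falling. Tim23 (295 to 348 TPM) and park (5.49 to 7.77 TPM) rose, and Tom20 (388 to 320 TPM) and Pink1 (31.2 to 26.1 TPM) fell. Pink1 lost its call without any of control replicates 3, 5 and 7 and TFAM RNAi replicates 4 and 8 (adjusted p up to 0.071). Of 13 mitochondrial chaperones and proteases, Afg3l2 fell (97.7 to 72.6 TPM), a call lost without control replicate 5 or TFAM RNAi replicate 4 or 8 (adjusted p up to 0.057) and absent when adjusted over the list alone. The median of this list, −0.12, turned to 0.09 under quantile normalization. Of 15 mitochondrial aminoacyl-tRNA synthetase genes, SerRS-m (33.9 to 21.9 TPM) and ProRS-m (10.4 to 7.6 TPM) fell, also when adjusted over the list alone. Median-ratio scaling ended the calls of Tim23, Tom20, Pink1, Mdh2 and Scsalpha1 (adjusted p from 0.1 to 0.29), and quantile normalization those of Tom20, Pink1, Mpc1, Scsalpha1, Afg3l2 and ProRS-m (adjusted p from 0.061 to 0.54). Mpc1 and Pink1 were also not called without the 4 libraries (adjusted p = 0.051 and 0.14), nor Pink1 with array weights (0.053) or Afg3l2 by the rank-sum test (0.11). Camera called none of these 3 lists (adjusted p = 0.85, 0.34 and 0.34).

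Of 15 genes of glycolysis and lactate dehydrogenase, 5 rose and 0 fell (7 rose when adjusted over the list alone), and all 15 had a positive log2 fold change; 2 rose under median-ratio scaling and 9 under quantile normalization (camera adjusted p = 2e-04; adjusted p = 0.73 with an estimated correlation). Aldolase (Ald1) rose from 970 ± 91.9 to 1528 ± 231 TPM (log2 fold change 0.64, adjusted p = 8.5e-04), Tpi from 492 to 666.5 TPM, Gapdh1 from 1655 to 1991 TPM and hexokinase A (Hex-A) from 27.8 to 49.2 TPM. Lactate dehydrogenase (Ldh) had 15.7 ± 15.7 TPM in control and 13.3 ± 4.39 TPM in TFAM RNAi and was not called (log2 fold change 0.14, adjusted p = 0.88); its log2 fold change ranged from −0.15 to 0.52 with single libraries left out. Tpi and Gapdh1 were not called under median-ratio scaling (adjusted p = 0.054 and 0.19). Among 11 genes of trehalose, glycogen and sugar sensing, 4 rose and 3 fell (5 and 3 adjusted over the list alone). The maltase-like gene tobi rose from 0.648 ± 0.505 to 16.7 ± 5.63 TPM, glycogen phosphorylase (Glyp) from 56.5 to 118 TPM and trehalase (Treh) from 19.8 to 30.0 TPM. The sugar-responsive factor sugarbabe (sug) fell from 163 to 46.5 TPM, with Mondo (149 to 88.5 TPM) and the glycogen branching enzyme AGBE (834 to 496 TPM). Without the 4 libraries Mondo and AGBE were not called (adjusted p = 0.052 and 0.056), nor was AGBE by the rank-sum test (0.11). Of 20 lipolysis and fatty acid oxidation genes 4 rose and 3 fell (4 and 4 adjusted over the list alone), among them Mcad, a medium-chain acyl-CoA dehydrogenase (72.4 to 166 TPM, log2 fold change 1.19), and the peroxisomal oxidase gene Acox57D-p (48.5 to 28.7 TPM). The lipase gene bmm had 5.41 and 7.88 TPM and was not called (adjusted p = 0.25). Of 17 lipid synthesis and lipid droplet genes 3 rose and 3 fell (4 and 3 adjusted over the list alone). The perilipin gene Lsd-1 fell from 1480 ± 318 to 800 ± 25.7 TPM, FASN2 from 10.5 to 4.07 TPM and AcCoAS from 1401 to 1068 TPM; the last 2 were not called without the 4 libraries (adjusted p = 0.054 and 0.055). Camera called none of these last 3 lists (adjusted p = 0.28, 0.34 and 0.75). The trehalose list was called by fry (adjusted p = 0.034). Quantile normalization gave 7 rises and 1 fall for lipolysis and 6 and 3 for lipid synthesis, and median-ratio scaling 2 and 2, and 3 and 3. For the lipid synthesis list the camera and mean directions were higher and that of fry lower.

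Of 11 genes listed in advance as fat-body-derived growth and endocrine signals, 2 rose and 5 fell, the same as when adjusted over the list alone. The name of the list does not establish the fat body as the usual source of each signal. Camera gave an adjusted p of 0.14 and called the list lower with no filter (0.018), as did fry (3.1e-04). The tumour necrosis factor ligand eiger (egr) fell from 94.0 ± 24.9 to 26.3 ± 5.57 TPM (log2 fold change −1.79, SE 0.18, adjusted p = 1.2e-05). Limostatin (Lst), a hormone that restrains insulin-like peptide release, fell from 329 ± 86 to 52.6 ± 15.9 TPM (log2 fold change −2.63). The nutrient-responsive peptide gene CCHa2 fell from 440 ± 136 to 184 ± 41.9 TPM, the insulin-binding protein gene ImpL2 from 47.4 ± 13.6 to 18.6 ± 10.5 TPM and the BMP ligand gene gbb by 0.28 on the log2 scale. The call of gbb was lost under median-ratio scaling (adjusted p = 0.24) and quantile normalization (0.33), with no filter (0.054), without the 4 libraries (0.12), and without any of control replicates 2, 3, 6 and 7 and TFAM RNAi replicates 4 to 8 (up to 0.1). The growth-blocking peptide genes Gbp1 (13.2 ± 2.15 to 19.6 ± 3.01 TPM) and Gbp2 (202 ± 19.9 to 310.0 ± 13.4 TPM, log2 fold change 0.62) rose. The activin-like ligand gene daw (39.0 and 27.6 TPM, adjusted p = 0.36) and Ilp6 (12.3 and 10.6 TPM, adjusted p = 0.68) were not called. The cytokine gene upd2 lay below the expression filter at 0.763 ± 0.311 and 0.0302 ± 0.0229 TPM; with no filter its log2 fold change was −0.76 (adjusted p = 1.7e-04). Of 10 JAK-STAT pathway genes 3 fell and 0 rose, 3 adjusted over the list alone: the ligand gene upd1 (9.0 to 0.166 TPM), the stress peptide gene TotC (73.9 to 1.7 TPM) and Socs36E (8.47 to 3.54 TPM; camera adjusted p = 0.12, and called lower with no filter, 0.0015, and by fry, 0.0035). Of 11 TNF and JNK pathway genes 5 fell and 0 rose, 5 adjusted over the list alone: egr, which stands on both lists, Tak1 (18.5 to 8.64 TPM), the AP-1 genes kay (log2 fold change −0.95) and Jra (17.9 to 12.1 TPM), and Mmp1 (7.56 to 3.99 TPM; camera adjusted p = 0.092). Mmp1 lost its call in 9 of the 12 fits without 1 library, all but those without control replicate 6 or 8 or TFAM RNAi replicate 7 (adjusted p up to 0.11), and without the 4 libraries (0.24). Its call was also lost with other pseudocounts, with no filter, without the trend, with the robust option and with array weights (adjusted p from 0.05 to 0.077). The rank-sum test called 2 genes of this list and not kay, Mmp1 or Jra (adjusted p = 0.11, 0.11 and 0.071). The calls of kay and Jra were lost without the 4 libraries (adjusted p = 0.085 and 0.12), where 2 genes of this list fell. Camera called the TNF and JNK list lower without control replicate 6 (adjusted p = 0.04), under median-ratio scaling (0.039) and quantile normalization (0.0097), with no filter (0.014) and at 5 TPM (0.049), as did fry (0.034). Of 12 FOXO and insulin-response genes Lip4 rose (9.96 to 27.0 TPM) and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.34). Thor, the 4E-BP gene on that list, had 104 ± 66.5 and 84.9 ± 26.0 TPM (adjusted p = 0.79); its sign turned under quantile normalization (log2 fold change 0.042).

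Of 23 antimicrobial peptide and humoral effector genes 9 rose and 3 fell (10 and 3 adjusted over the list alone). Besides DptB, DptA, AttC and PGRP-SB1, the rises were Dro (0.863 to 46.1 TPM), Mtk (45.8 to 213 TPM), AttB (3.58 to 35.5 TPM), edin (0.0779 to 18.8 TPM) and PGRP-SD (77.3 to 138 TPM). The falls were PGRP-SC2, the recognition protein gene PGRP-SA (98.9 to 69.6 TPM) and the serpin gene nec (127 to 73.6 TPM). PGRP-SA was not called under median-ratio scaling (adjusted p = 0.064), quantile normalization (0.1) or without the 4 libraries (0.062), nor by the rank-sum test (0.071), which also did not call AttB (0.15). AttB was not called without any of control replicates 6 and 7 and TFAM RNAi replicates 6 and 8 (adjusted p up to 0.061). Without TFAM RNAi replicate 6 the TFAM RNAi means were 37.6 TPM for DptA and 7.77 TPM for edin, and 23.25 TPM for AttB. Without control replicate 3 the control means of Dro and edin were 0.492 and 0.049 TPM, and without control replicate 2 that of DptA was 0.18 TPM. Camera called the list higher (adjusted p = 0.025; adjusted p = 0.73 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.089), 5 (0.076) or 8 (0.051) or TFAM RNAi replicate 3 (0.11), and without the 4 libraries richest in markers of other tissues (0.33), where 10 members rose and 3 fell. It was also lost under quantile normalization (0.08) and with array weights (0.12). Fry did not call the list (adjusted p = 0.31).

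Of 8 larval serum and lipoprotein genes of the fat body 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.73 with an estimated correlation). Besides Lsp1alpha these were fat body protein 2 (Fbp2, 142 ± 118 to 2089 ± 1119 TPM, log2 fold change 4.17) and Mtp (196.5 to 318 TPM). Lsp2 had 4050 ± 2128 and 4741 ± 1518 TPM and was not called (adjusted p = 0.56). Of 6 ecdysone response genes Eip74EF rose (1.76 to 6.09 TPM) and 0 fell (3 rose when adjusted over the list alone; camera adjusted p = 0.085). Camera called this list higher without control replicate 5 (adjusted p = 0.038) or TFAM RNAi replicate 3 (0.024) and with no filter (0.03).

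Of 30 glutathione S-transferase genes 9 fell and 5 rose (11 and 5 adjusted over the list alone; camera adjusted p = 0.094). Camera called the list lower without control replicate 2 (adjusted p = 0.04) or TFAM RNAi replicate 3 (0.03) or 4 (0.034), with no filter (0.023), with array weights (0.0058) and without the 4 libraries (9.7e-04), as did fry (3.6e-04). Quantile normalization gave 8 falls and 7 rises and median-ratio scaling 9 and 2. GstD5 fell from 165 ± 52 to 5.8 ± 1.63 TPM (log2 fold change −4.58, adjusted p = 9.2e-09), GstE9 from 625 to 254 TPM, and GstE11 and GstE8 by 1.26 and 1.3 on the log2 scale. Of 16 antioxidant enzyme genes 8 fell and 2 rose (8 and 4 adjusted over the list alone; camera adjusted p = 0.19; called by fry, 3.1e-04), whereas 6 fell and 5 rose under quantile normalization and 5 and 1 under median-ratio scaling. Thioredoxin Trx2 fell from 1002 ± 109 to 508.5 ± 65.5 TPM and thioredoxin reductase Trxr1 from 240 to 136 TPM, whereas catalase (Cat) rose by 0.97 on the log2 scale. Of 57 cytochrome P450 genes 15 rose and 11 fell (18 and 17 adjusted over the list alone; camera adjusted p = 0.19), and the list's median, 0.01, turned to −0.01 under quantile normalization. Camera called it without control replicate 3 (adjusted p = 0.029) and with a filter at 5 TPM (0.013). Cyp6a23 rose from 6.43 to 43.7 TPM, Cyp28a5 by 2.34 on the log2 scale and Cyp4d1 from 163 to 333 TPM, and Cyp4d14 fell from 154.5 to 33.3 TPM. Of 15 ATF4 and integrated stress response genes 5 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.094). Without the 4 libraries 2 fell and 1 rose, and under quantile normalization 3 and 2. Camera called the list lower without control replicate 2 (adjusted p = 0.048) and with no filter (0.018), as did fry (0.0035). The falls included CG11899, the phosphoserine aminotransferase gene of serine synthesis (327 ± 69.3 to 61.5 ± 10.8 TPM, log2 fold change −2.38), and asparagine synthetase (AsnS, 443 to 253 TPM).

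**Figure D2:**
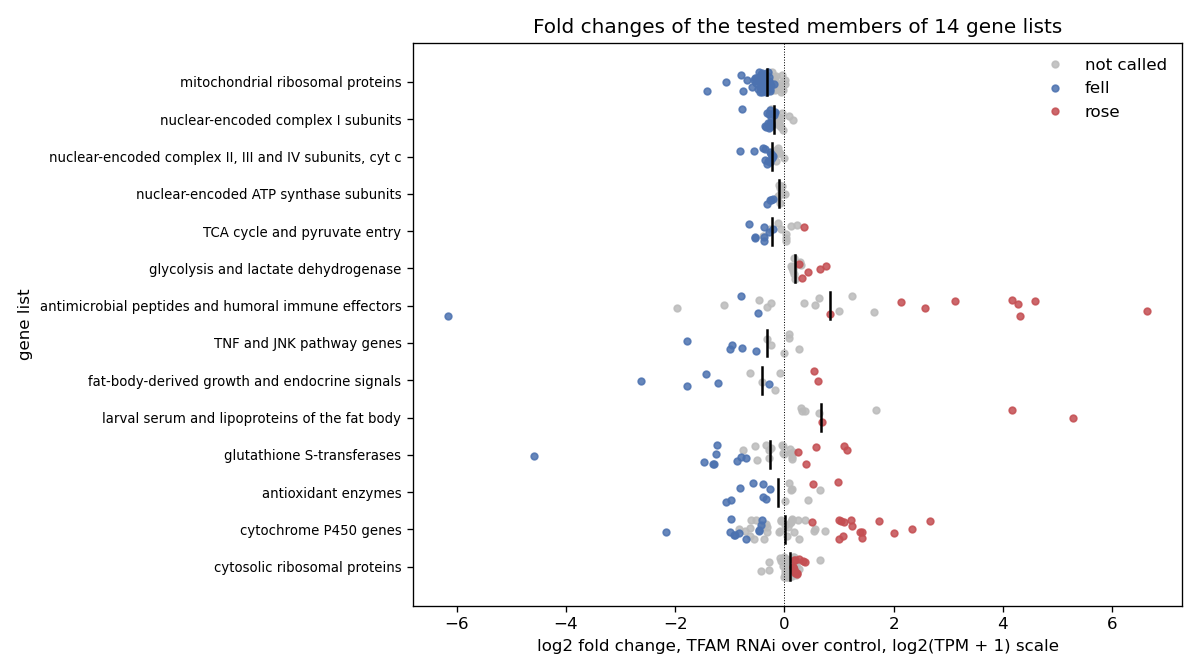
Log2 fold changes (TFAM RNAi over control, log2(TPM + 1) scale) of the tested members of 14 gene lists, 1 point per gene, coloured by the call of the gene test, with a bar at each list's median. The mitochondrial ribosomal protein genes lie mostly left of 0 (median −0.31, 47 of 75 fell), and the antimicrobial peptide genes extend to 6.64 (DptB) and −6.16 (PGRP-SC2).

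Of 85 cytosolic ribosomal protein genes 12 rose and 0 fell, also when adjusted over the list alone, at a median log2 fold change of 0.11, but 1 rose under median-ratio scaling and 6 without the 4 libraries. RpS2 rose from 2458 to 3208 TPM and RpL15 from 3113 to 3673 TPM. Camera called the list higher (adjusted p = 9e-07; adjusted p = 0.73 with an estimated correlation), but quantile normalization turned it lower (adjusted p = 0.048), with 3 members rising and 11 falling. Camera's call was lost with array weights (adjusted p = 0.071), and fry did not call the list (adjusted p = 0.084). The call of RpL15 was lost under both scalings (adjusted p = 0.29 and 0.15). Of 20 cytosolic aminoacyl-tRNA synthetase genes CysRS rose (29.5 to 36.4 TPM) and HisRS fell (145 to 105 TPM), also when adjusted over the list alone. Camera called this list higher (adjusted p = 0.024, and 0.81 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.17), with array weights (0.06) and without the 4 libraries (0.1). Fry did not call the list (adjusted p = 0.24). Under median-ratio scaling neither CysRS nor HisRS was called, and under quantile normalization 14 members rose and 1 fell. By limma 0 of 18 ribosome biogenesis genes were called, also with adjustment over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by the rank-sum test, and camera gave an adjusted p of 0.28; under quantile normalization 4 rose, and camera called the list there (0.0097) and without control replicate 6 (0.042). Of 14 heat shock protein genes Hsp70Bbb fell, at 27.1 ± 35.2 and 0.767 ± 0.764 TPM, a call lost without any of control replicates 5, 7 and 8 and TFAM RNAi replicates 4 to 7 (adjusted p up to 0.075) and when adjusted over the list alone (camera adjusted p = 0.28); its control mean was 17.99 TPM without replicate 5. It was also not called with no filter (adjusted p = 0.053) or without the 4 libraries (0.051). Of 16 autophagy genes Atg17 rose (4.09 to 9.46 TPM; camera adjusted p = 0.34), and of 7 hypoxia response genes the prolyl hydroxylase gene Hph fell (21.4 to 10.3 TPM; camera adjusted p = 0.94); both calls held when adjusted over the list alone. The hypoxia list had a median of 0.09 and a mean of −0.1.

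The summed TPM of 16 muscle markers was 3773 in control replicate 2 and 316 to 1231 in the other 11 libraries. That of 15 midgut markers was 11580 in control replicate 3 and 6790 in TFAM RNAi replicate 4, against 438 to 3707 in the others. The summed TPM of 9 salivary gland markers was 3145 in TFAM RNAi replicate 3, hardly above the 3125 in control replicate 8, with 2709 in control replicate 6. The fit without the 4 libraries left out the first of these and kept the other libraries named. The salivary glue gene Sgs7 had 767 TPM in TFAM RNAi replicate 3 and at most 15.8 TPM in the other TFAM RNAi libraries. Of the midgut markers the trypsin genes betaTry (5.5 ± 6.55 to 98.8 ± 103.5 TPM) and epsilonTry (0.379 ± 0.285 to 55.5 ± 109.6 TPM) rose and 0 fell, with a median of −0.34, a mean of 0.03 and a camera direction of higher (adjusted p = 0.97). Without TFAM RNAi replicate 4 the TFAM RNAi means were 62.5 TPM for betaTry and 11.0 TPM for epsilonTry, and without control replicate 3 the control mean of betaTry was 2.88 TPM. Of 10 hemocyte markers Pxn, the peroxidasin gene, fell (136 ± 71.8 to 5.28 ± 1.37 TPM) and 0 rose, with a median of 0.16, a mean of −0.22 and a camera direction of higher (adjusted p = 0.77). Of 12 testis and germline markers Mst84Db rose (13.5 to 27.2 TPM; camera adjusted p = 0.23), a call lost without any of control replicates 3, 5, 6, 7 and 8 and TFAM RNAi replicates 5 to 8 (adjusted p up to 0.085) and when adjusted over the list alone. It was also not called with no filter (adjusted p = 0.057) or by the rank-sum test (0.21), and its control mean was 8.21 TPM without control replicate 2. Without the 4 libraries 3 of the 12 rose, at a median of 0.8, and camera called this list higher (adjusted p = 0.047). Of 6 imaginal disc markers Ubx rose (0.743 to 2.69 TPM) and dpp fell (1.86 to 0.783 TPM), the latter lost without any of control replicates 5 and 7 and TFAM RNAi replicates 4 and 8 (adjusted p up to 0.059), as without the 4 libraries (0.12). This list had a median of −0.03, a mean of 0.04 and a camera direction of higher (adjusted p = 0.94). Of the neuronal markers, too few to test as a list, Syt1 rose (23.1 to 28.4 TPM), a call lost without any of control replicates 2, 5, 6, 7 and 8 and TFAM RNAi replicates 3, 4, 7 and 8 (adjusted p up to 0.11), as under median-ratio scaling, with no filter, without the trend, with array weights and without the 4 libraries (from 0.052 to 0.25). None of the tested markers of body wall muscle (16), salivary gland (9), epidermis and trachea (7) or sex composition (4) was called by limma, where 0, 0, 1 and 0 had an unadjusted p under 0.05 and 0 were called by the rank-sum test. With all libraries camera called none of the lists of other tissues; the muscle list had a median of −0.16, a mean of −0.11 and a camera direction of higher (adjusted p = 0.97).

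The authors' deposited tables list 1561 gene names and 1758 transcripts with a likelihood ratio q under 0.05. In the authors' deposited table of transcripts 544 coefficients were positive and 1214 negative. Named by accession, these transcripts belong to 1383 genes, of which 1323 were tested here and 1115 were called, 1104 of them in the direction given in the authors' deposited table. Independent lists of these sizes would share 259 genes. Both lists came from the same 12 libraries and the same groups, so their overlap is no independent check. The coefficient of CG14752 in the authors' deposited table, −6.22, is a ratio of 0.00198 as a natural log and 0.0134 as a log2 value; the ratio of mean TPM was 0.00199.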

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

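The tests of scaling, fat body share, midgut RNA, immune response in a few libraries, chromosome arm 2R and larval stage were chosen only after the result they bear on was seen, as were the repeated draws for transcript length and the wider reading of a shared name. Of 278 groups of 6 values examined, 21 held a library whose gap to the nearest other was large against the group's range by Dixon's test; chance alone sets apart about 1 in 20 groups, here 13.9.

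Among the TFAM RNAi libraries, replicate 3 stood apart 9 times. It was lowest for Ilp6 (5.93 TPM), Thor (37.8 TPM), Ald1 (1066 TPM), Tak1 (5.84 TPM) and Eip74EF (2.83 TPM), and highest for mRpL36 (142 TPM), Trx2 (637 TPM) and Sgs7 (767 TPM). The 9th was its share of ribosomal protein transcripts, the highest at 30.5% against 25.4 to 26.9% in the others. TFAM RNAi replicate 4 was highest for Socs36E (6.64 TPM) and lowest for sug (15.7 TPM), replicate 5 highest for PGRP-SC2 (11.4 TPM), replicate 7 highest for CG14949 (3.38 TPM) and replicate 8 lowest for ATPsynE (895 TPM). Among the controls, replicate 2 was highest for lectin-24A (7.98 TPM) and Mst84Db (40.1 TPM), and replicate 3 for Cyp6a23 (12.8 TPM). Control replicate 6 was lowest for Irbp18 (14.502 TPM) and highest for pit (56.4 TPM), and replicate 8 was lowest for mRpS2 (115 TPM) and mRpS23 (69.1 TPM).

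A chance division of the 12 libraries was argued against as the source of the gene counts. In 100 of the 462 splits into 6 and 6, 1 gave as many as 1949 called genes, the real one, and the highest other gave 1194. The splits treat the libraries as independent, which the labels do not state. A chance difference between cultures shared within a group was therefore not excluded. For changes of at least 2-fold 1 split reached 586 and the highest other gave 293. The highest other in both cases exchanged control replicate 5 for TFAM RNAi replicate 3. Chance was not excluded for the number of called lists: 88 of 100 splits gave 10 or more with camera at the preset correlation, and the highest gave 20. The number of called lists is therefore no evidence of a difference between the groups. Among lists called by camera, 2 of 100 splits, the real one included, gave as many called members for complex I (17, highest other 19), complexes II to IV (13, highest other 13), ATP synthase (4, highest other 6), larval serum proteins (3, highest other 6) and cytosolic aminoacyl-tRNA synthetases (1, highest other 8).

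The fall of mitochondrial ribosomal protein genes, 47 of 75, was reached in 1 of 100 splits, the real one, and the highest other split gave 37 in 1 direction. The larval serum and lipoprotein genes had a median log2 fold change of 0.667, which speaks against a smaller share of fat body RNA, but that share stays open because a stage difference could raise those genes. A loss of short transcripts in the TFAM RNAi libraries stays open as a part of the fall: genes matched on length had a median of −0.048 (95% of draws from −0.156 to 0.074) against −0.31 for the list, but the lower limit met the line set beforehand for excluding it (−0.156) and lay above it in only 6 of 20 repeats. The scaling of TPM between libraries remains open, since under quantile normalization 14 fell and 2 rose and the median shrank from −0.31 to −0.10, whereas under median-ratio scaling 14 fell but the median stayed at −0.30. An effect of TFAM knockdown is the other open explanation and was not tested apart from the stock.

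The rise of antimicrobial peptide genes, 9 members, was reached in 1 of 100 splits, and the highest other gave 0. RNA from midgut, which also expresses such peptides, was argued against: the midgut markers had a median log2 fold change of −0.343 (SE 0.367), below the smallest rise of 0.83 for PGRP-SD. That rise is the smallest among genes chosen by their call. The SE came from resampling the 15 midgut markers as if independent, although their estimated inter-gene correlation was 0.509. It therefore leaves out spread that the markers share between libraries and is likely too small. Of these markers betaTry and epsilonTry rose, but the more abundant Jon65Aiv (1119 and 838 TPM) and deltaTry (956 and 703 TPM) did not, and control replicate 3, with the most midgut marker TPM, had 0.201 TPM of DptB. A response in a few libraries only stays open. DptB had at least 54.9 TPM in each TFAM RNAi library and at most 4.2 in control, PGRP-SB1 39.0 and 5.92, and AttC 23.3 and 8.99. These genes were named because their groups did not overlap, so their separation cannot decide the question. Of the 23 tested members 8 to 14 lay above all 6 controls in each TFAM RNAi library. In control replicate 3, the library richest in midgut markers, 9 lay above the other 5 controls. A difference in exposure to microbes between the cultures of the groups cannot be separated from the knockdown in this design and was not tested.

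Changes of at least 8-fold were found in 79 called genes, 22 higher and 57 lower. A chromosome block that differs between the stocks cannot be told apart from the knockdown: 5 pairs of these genes without a shared name lay within 5 tested genes of each other, against a median of 3 and a 95th percentile of 6 in random sets, but the narrower reading of a shared name used first gave 7, above its 95th percentile of 6 (48 of 1000 random sets gave as many). Chromosome arm 2R held 166 of the 585 placed genes with at least a 2-fold change, above the highest of 10000 random sets matched on expression (160), but 82 of 341 without listed genes and name-sharing families, where the 95th percentile was 83, so a stock difference along this arm stays open. Scattered strain variants also stay open, with 8 of the 79 genes under 0.5 TPM in all libraries of 1 group. For the rise of Lsp1alpha by 5.28, a different larval stage stays open. The largest log2 fold change among Lsp1beta, Lsp1gamma and Lsp2 was 0.641, which speaks against a stage shift that moves these genes alike, but Lsp1beta and Lsp1gamma already stood above Lsp1alpha in control. Fbp2 rose by 4.17 and Eip74EF by 1.37, and the 6 ecdysone response genes had a median of 0.67.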

How the results depend on the processing

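The fits without the 4 libraries richest in markers of other tissues, and of 10 libraries without the block, were chosen after the data were seen. Depth is unknown, so what it limits could not be computed. TFAM kept its direction and call in all other fits run for it, with log2 fold changes from −1.92 to −1.70. The count of called genes was 1949 and lay between 1641 and 2159 with single libraries left out. Array weights gave 4648 called genes, 2633 of them higher, and 952 with at least a 2-fold change. Genes called higher numbered 572 in all libraries, 961 under quantile normalization, 1137 without the 4 libraries and 884 in 10 libraries without a block. The number of called lists was 10, 17 with no filter and 0 with an estimated correlation. The cause of these differences was not tested. The rescaling that leaves out mitochondrially encoded genes would remove no gene and was not run, and camera was not run with the robust option or the rank-sum test.

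Of 111 named genes called by limma, 74 were called in all fits run, 37 lost the call in at least 1 fit and 0 changed sign. Calls lost numbered 24 under median-ratio scaling, 15 under quantile normalization, 13 without the 4 libraries and 6 with the replicate block. Of 10 called lists 4 kept their call in all fits but the estimated correlation: complexes II to IV, mitochondrial ribosomal proteins, glycolysis and larval serum proteins. Of the 28 lists not called, 12 were called in at least 1 other fit.

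The 5 replicate numbers that occur in both groups were not shown to pair all of the libraries. Correlations of deviations from the group means were 0.313 for number 3, 0.616 for 5, −0.077 for 6, 0.047 for 7 and 0.035 for 8, and of the 5 controls that of number 5 alone correlated best with its own number. With a replicate block over these 10 libraries 2510 genes were called, 1342 higher and 1168 lower, and in the same libraries without it 1987, 884 higher and 1103 lower. With the block and without it camera called glutathione S-transferases (adjusted p = 0.0043 and 0.011), the TCA cycle (0.021 and 0.033), ATF4 genes (0.037 and 0.042), TNF and JNK (0.044 and 0.044) and testis markers (0.016 and 0.042), but not antimicrobial peptides (0.15 and 0.147) or cytosolic aminoacyl-tRNA synthetases (0.13 and 0.19). Of the named genes called by limma the block ended the calls of ATPsynE (adjusted p = 0.052), Pink1 (0.092), CysRS (0.054), Jra (0.051), Agpat3 (0.11) and RpL18 (0.059), and also those of gbb (0.15) and Mmp1 (0.11). Without it Pink1, Hex-A, Agpat3, Syt1, dpp, gbb and Mmp1 lost theirs (adjusted p from 0.057 to 0.12). With the block 4 cytosolic ribosomal protein genes rose. Endocrine signals were called with the block alone (0.044) and JAK-STAT genes without it alone (0.044). Under the block Mlc2 had a log2 fold change of 0.14, the lists of import, lipid synthesis, midgut, epidermis and imaginal disc turned direction (adjusted p = 0.953, 0.92, 0.143, 0.973 and 0.883), and in the same libraries without it Mlc2 had 0.14 and the last 4 lists gave 0.917, 0.566, 0.968 and 0.917.

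Other turns of direction were of results not called in all libraries, except cytosolic ribosomal proteins under quantile normalization (adjusted p = 0.0483). Thor had log2 fold changes of 0.042 under quantile normalization, 0.196 without the 4 libraries and −0.33 to 0.094 with single libraries left out. Ldh ranged from −0.15 to 0.52 and Mlc2 from −0.63 to 0.11 with single libraries left out. Without the 4 libraries Ilp6 had 0.089 and Mlc2 0.011, and the lists of lipolysis (adjusted p = 0.728), midgut (0.528), salivary gland (0.595) and imaginal discs (0.985) turned. Camera's adjusted p for lists that turned were, with no filter, 0.997 for import, 0.997 for midgut and 0.861 for muscle; with a filter at 5 TPM, 0.831 for epidermis; under median-ratio scaling, 0.954 for midgut, 0.927 for muscle and 0.954 for discs; under quantile normalization, 0.758 for mitochondrial chaperones, 0.739 for midgut, 0.784 for muscle and 0.675 for discs; with array weights, 0.913 for midgut and 0.778 for muscle. Fry gave adjusted p = 0.956 for import, 0.897 for lipid synthesis, 0.519 for hemocytes, 0.897 for midgut, 0.897 for muscle and 0.943 for discs, all lower. With single libraries left out the adjusted p ranged from 0.563 to 0.983 for import, 0.726 to 0.985 for hypoxia, 0.389 to 0.97 for midgut, 0.261 to 0.988 for muscle, 0.455 to 0.986 for epidermis and 0.662 to 0.992 for discs.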

Other observations

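The 13 gene families below were chosen after the values were seen and tested with camera, adjusted over the 13. Of 8 Arp2/3 complex genes, which nucleate branched actin, 7 fell and 0 rose (adjusted p = 9.6e-04; adjusted p = 0.2 with an estimated correlation). Of 22 UDP-glycosyltransferase genes 8 fell and 0 rose (adjusted p = 0.0011; adjusted p = 0.2 with an estimated correlation). Of 44 proteasome genes 12 fell and 0 rose, and of 10 genes of the endoplasmic reticulum membrane protein complex 6 fell and 0 rose (adjusted p = 0.002 and 0.025; adjusted p = 0.51 and 0.41 with an estimated correlation). The falls were fewer under quantile normalization, at 2 Arp2/3, 7 UDP-glycosyltransferase, 1 proteasome and 1 membrane complex gene. Median-ratio scaling gave 3 Arp2/3, 6 proteasome and 2 membrane complex falls but kept the 8 of the UDP-glycosyltransferases. Of 19 neprilysin-like peptidase genes 8 fell and 3 rose (adjusted p = 0.013; adjusted p = 0.41 with an estimated correlation).

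Of 4 tested genes that restrain Imd signalling, the pathway that drives diptericin genes, PGRP-SC2, PGRP-LF and pirk fell and 0 rose (adjusted p = 9.6e-04; adjusted p = 0.2 with an estimated correlation). PGRP-LF and pirk had log2 fold changes of −1.88 and −3.4. Among 9 Bomanin and Daisho genes, which respond to Toll, BomS4 rose and BomS6 fell (adjusted p = 0.79). The metallothionein genes MtnB and MtnC rose, 2 of 6 tested (adjusted p = 0.062). The neighbouring odorant-binding protein genes Obp99a, Obp99b and Obp99c rose and Obp83ef fell, of 11 tested (adjusted p = 0.097); the family's median, −0.01, turned positive under both scalings, where Obp83ef was not called. Of 11 serpin genes the neighbours Spn42Da, Spn42Db and Spn42Dc rose and 6 fell (adjusted p = 0.12). Of 28 tetraspanin genes 7 fell and Tsp42Ek rose (adjusted p = 0.11). Of 14 peroxin genes 5 fell and Pex5 rose (adjusted p = 0.051). Of 8 genes of protein entry into the endoplasmic reticulum, Sec61gamma and TRAM rose and Spase22-23 and Spase12 fell (adjusted p = 0.25); the falls were not called under either scaling.

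Chosen after their values were seen, CG11898 and CG14515, neighbours on chromosome arm 3R, were both among the 8 genes under 0.5 TPM in all libraries of 1 group, at log2 fold changes of −4.24 and −3.76.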
